A study of Mus musculus with 9 samples.

How the data were processed

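RNA sequencing was done on 9 libraries of sorted cells from mouse fetal livers at embryonic day 14.5 (strain C57BL/6), 3 libraries in each of 3 groups. Per the labels, the Evi1 HSC group held GFP-positive cells of a haematopoietic stem cell (HSC) gate (lineage-negative, c-Kit-positive, Sca-1-positive, CD150-positive, CD48-negative) from embryos with a Tie2-Cre driver and a ROSA-Evi1 allele. Tie2-Cre is a recombinase active in endothelial and blood cells, and Evi1 is a zinc finger transcription factor encoded at the Mecom locus. The WT HSC group held the same surface gate, without the GFP criterion, from embryos with the ROSA-Evi1 allele and no Cre. The WT KL group held c-Kit-positive, Sca-1-negative, lineage-negative cells, a gate of committed progenitors, from that same genotype. Each library was made from the lysate of 100 cells, per the labels' protocols. No label says that the replicates of a group came from separate embryos or litters. Each group held libraries of both sexes by Xist and Ddx3y, so the libraries of a group were not all repeats of 1 embryo. Whether those of the same sex shared an embryo, or all shared a litter, is not known, and the p-values measure only the spread between these samples.

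The deposited values are TPM per gene, a length-scaled share of transcripts, per the file headers, with 1 library per file and none pooled. In 1 file, that of WT HSC replicate 2, the value column was headed C_H3, which no label explains, and its values were used as TPM because their sum and range matched those of the other 8. HISAT2, StringTie and the mouse build mm10 are named in the submitters' processing notes. Their roles and versions, the annotation and whether strand was used in counting are not given in the sources used here. TPM divides by gene length and by each library's total, so a few abundant genes that rise lower the values of all others. The listed genes summed to 56.9 to 63.8% of the TPM scale per library, so features outside the tables took the rest. TPM keeps no read depth: the depth is unknown here, no counting interval could be given, and a gene listed at 0 was not detected at an unknown depth. No count model was used for the same reason.

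Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3. Genes at 1 TPM or more in at least 3 of the 9 libraries were tested, which kept 19461 of 55488. One linear model with a mean per group was fitted over the 9 libraries, with moderated statistics that followed a trend with mean expression and with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Each fold change is a difference of mean log2(TPM + 1), which understates the change of low genes. The 3 comparisons were Evi1 HSC against WT HSC, WT HSC against WT KL, and Evi1 HSC against WT KL, and the last 2 share the WT KL libraries. Groups, comparisons, tests, the naming rule, 22 gene lists and most alternatives were set before the data were examined. On simulated data with the same 19461 genes, in which 100 genes changed 2-fold and 100 changed 4-fold, the fit over 9 libraries recovered 53, 50 and 60% of the 2-fold and 86, 82 and 86% of the 4-fold changes in the 3 comparisons, in that order. With 7 libraries it recovered 30, 25 and 20% and 70, 69 and 72%, and false calls numbered 5 to 10. Both simulations took each gene's spread from the real fit over 7 libraries, and no simulated library went against its label. The recovery with 9 libraries therefore does not describe the real fit over 9 libraries as labelled. There the SE of Mecom in the first comparison was 2.18, against 0.20 over 7 libraries.

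Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 17 lists and 3 comparisons (51 tests), with camera at an estimated correlation and limma's fry as alternatives. The lists were haematopoietic stem cell, reported Evi1 targets, Hox cluster, fetal programme, erythroid, megakaryocyte, granulocyte and monocyte, lymphoid, endothelial, arterial and haemogenic endothelium, S phase, G2 and M phase, immediate early, interferon response, TGF-beta signalling, ribosomal proteins, and mitochondrially encoded genes. Another 5 lists, for mast cells, basophils and eosinophils, macrophages, hepatocytes, stroma and MHC class II, had fewer than 5 members past the filter and were not tested. Some lists share members, such as Esam, Tek and Robo4 in the stem cell and endothelial lists, and many endothelial markers are also used by stem cells. Of all listed symbols, Ahsp had no match in the tables, so 26 of 27 erythroid genes were looked up.

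Mecom and the gate genes Ly6a (Sca-1), Kit, Slamf1 (CD150) and Cd48 were named in every library. Per comparison, the naming rule took the 10 genes with the largest rise and the 10 with the largest fall among called genes, with a mean of at least 10 TPM in the higher group and no overlap between the libraries. It left out predicted and clone-named genes, and some genes that it took are not reported here. Where under 5 qualified, it filled up to 5 by smallest p. It also took up to 4 members per list, or 2 by level where none was called. Those last members are not named one by one for lists that did not pass, a choice made after fold changes near 0 were seen to change sign between settings.

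In the order of the numbers in their file names, 4 of the 6 WT libraries fit an alternation of WT HSC and WT KL. An alternative set in advance left out the 2 that break it as labelled. That alternative is given beside each result because those libraries, labelled WT HSC replicate 3 and WT KL replicate 1, went against their labels in the gate genes. The alternatives run on these 7 libraries were added after seeing the data. The other alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios rescaling, quantile normalisation, a fit on the compared groups alone, array weights, a replicate block, and leaving out each library in turn. Coordinates came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. It held 55227 of the gene identifiers (99.5%). The reporter Egfp has no coordinates in it, and 234 symbols occur more than once.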

Results

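Gene expression was measured in 3 libraries each of Evi1 HSC, WT HSC and WT KL cells from day 14.5 fetal livers, with 100 sorted cells per library. Between 18258 and 18806 genes reached 1 TPM in 6 of the libraries. In the other 3, the library labelled WT HSC replicate 3 and WT KL replicates 2 and 3, the number was 15422 to 15819. The 10 most abundant genes held 24.3 to 27.6% of the listed TPM in each library.

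Mecom, the gene of Evi1, stood at 209, 176 and 210 TPM in the Evi1 HSC libraries, a mean of 198 ± 19 (SD, n = 3). It lies on chromosome 3 from 29951296 to 30548008 on the minus strand, and 81 of its 12427 exonic bases are shared with Mecomos. WT HSC replicates 1 and 2 held 161 and 114 TPM, and WT KL replicates 2 and 3 held 0.0107 and 0.325 TPM. The library labelled WT HSC replicate 3 held 0.0167 TPM, and the library labelled WT KL replicate 1 held 90.8 TPM, each against its label. Whether reads of the transgene were counted to Mecom is not given in the sources used here. Ly6a, which encodes the gate marker Sca-1, was at 13.2 and 17.6 TPM in WT HSC replicates 1 and 2. It was listed at 0 in the library labelled WT HSC replicate 3 and stood at 19.7 TPM in the library labelled WT KL replicate 1. Hlf, a stem cell transcription factor, was at 0.631 TPM in the library labelled WT HSC replicate 3 and at 164 TPM in the library labelled WT KL replicate 1. Mpo, the myeloperoxidase of granulocyte precursors, was at 579 and 13.6 TPM in these libraries, in that order. Egfp, the reporter that the Evi1 HSC gate selected on, was at 23.4, 27.3 and 25.4 TPM in the Evi1 HSC libraries (25.3 ± 1.96, SD, n = 3). In the 6 WT libraries it was at 0 to 0.380 TPM.

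**Figure D1:**
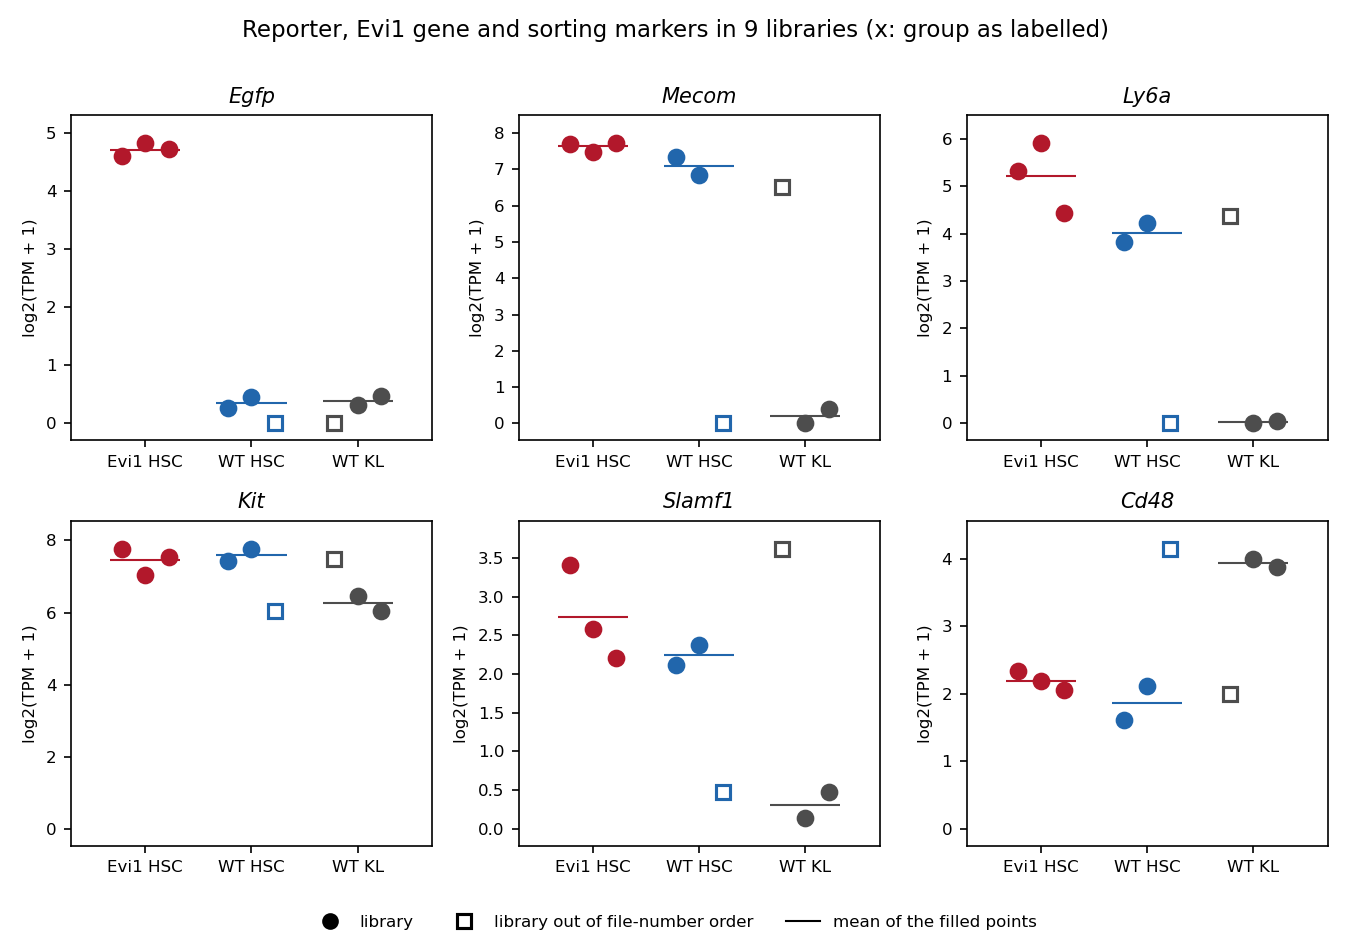
Values as log2(TPM + 1) per library for Egfp, Mecom, Ly6a, Kit, Slamf1 and Cd48, with the libraries grouped as labelled. Open squares are the 2 WT libraries out of file-number order, and lines are the mean of the filled points on that scale. Mecom is at 0.0167 TPM in the library labelled WT HSC replicate 3 and at 90.8 TPM in the library labelled WT KL replicate 1.

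Across genes, the library labelled WT HSC replicate 3 had a mean Pearson r of 0.972 with WT KL replicates 2 and 3 and of 0.832 with WT HSC replicates 1 and 2. The library labelled WT KL replicate 1 had a mean r of 0.955 with WT HSC replicates 1 and 2 and of 0.827 with WT KL replicates 2 and 3. Among the remaining libraries, the lowest r within a group was 0.944. Genes are not independent replicates, so no p is given. The groups were kept as labelled in the fits over 9 libraries, and values without these 2 libraries, which leave 2 libraries in each WT group, follow each of them.

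**Figure D2:**
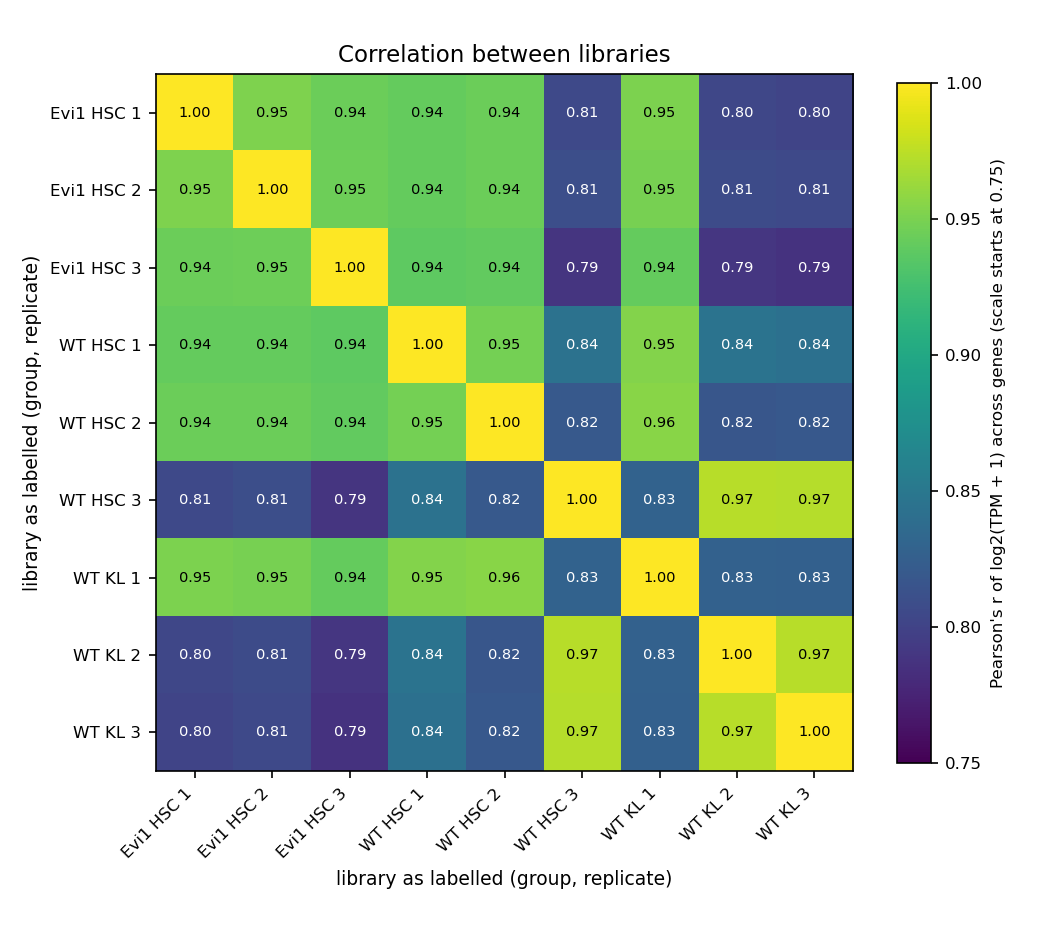
Pearson r between each pair of the 9 libraries over the 19461 tested genes on the log2(TPM + 1) scale, with a colour scale that starts at 0.75. The library labelled WT HSC replicate 3 has a mean r of 0.972 with WT KL replicates 2 and 3, and the library labelled WT KL replicate 1 has a mean r of 0.955 with WT HSC replicates 1 and 2.

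The comparison of Evi1 HSC with WT HSC addresses what stem cells carrying ectopic Evi1 express compared with stem cells of the same surface phenotype without it. With all 9 libraries as labelled, Egfp was the 1 gene called. It was higher in 3 of 3 Evi1 HSC libraries by 4.48 (SE 0.24) on the log2 scale (adjusted p = 6.5e-04), a difference that the GFP gate sets. It was not called with a pseudocount of 0.1 (adjusted p = 0.33, against 4.5e-06 to 0.031 in its other alternatives). Mecom differed by 2.90 (SE 2.18, adjusted p = 0.791), less than the spread between the libraries labelled WT HSC. The other gate genes had adjusted p of 0.791 to 0.847. At an unadjusted p under 0.05, 907 of the 19461 tested genes differed, fewer than the share of 0.05 that chance gives. Genes that the naming rule took by p, and that did not pass, included Foxj3 at 1.73 (adjusted p = 0.554) and Dpy19l1 at −1.58 (adjusted p = 0.409). The count was 3 without WT HSC replicate 2 and 3 without the library labelled WT HSC replicate 3.

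Without the 2 libraries that went against their labels, 40 genes were called, 11 higher and 29 lower in Evi1 HSC, and the lower ones included erythroid genes. Gata1, a master transcription factor of red cell formation, was at 4.20, 3.79 and 2.79 TPM in Evi1 HSC and at 17.3 and 18.2 TPM in WT HSC replicates 1 and 2. Its log2 fold change was −2.04 (SE 0.17, adjusted p = 0.018). Klf1, the erythroid Krüppel-like factor, fell by 3.69 (SE 0.45, adjusted p = 0.043). Epor, the erythropoietin receptor, fell by 1.36 (SE 0.15, adjusted p = 0.039), and Ermap, a red cell membrane protein, fell by 4.35 (SE 0.42, adjusted p = 0.031). Pklr, the red cell and liver pyruvate kinase, fell by 4.52 (SE 0.48, adjusted p = 0.039), and the heme-binding Hebp1 fell by 2.60 (SE 0.15, adjusted p = 0.0026). Other lower genes were Atp1b2 at −3.20, Nxpe2 at −2.93, the iron exporter Slc40a1 at −2.08, Dnajb4 at −1.75, Nmnat3 at −1.65 and Cgrrf1 at −1.58 (adjusted p of 0.010 to 0.039).

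In GRCm38, Gata1 lies on chromosome X from 7959260 to 7978071 (minus strand) and Klf1 on chromosome 8 from 84901928 to 84905291 (plus strand). Epor lies on chromosome 9 from 21958897 to 21963506 (minus strand) and Ermap on chromosome 4 from 119175457 to 119190011 (minus strand). Pklr lies on chromosome 3 from 89136142 to 89146784 (plus strand) and shares 711 of 3236 exonic bases with Hcn3, so its values are less certain. Hebp1 lies on chromosome 6 from 135137522 to 135198022 (minus strand). Of the genes that were higher, Cenpp lies on chromosome 13 from 49464023 to 49652785 (minus strand) and shares 322 of 2564 exonic bases with Aspn and Ippk. Csrp1 lies on chromosome 1 from 135720061 to 135752232 and Mt1 on chromosome 8 from 94179082 to 94180327, both on the plus strand.

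Genes higher in Evi1 HSC in that fit included Egfp by 4.36. The centromere gene Cenpp was higher by 3.20 (SE 0.16, adjusted p = 0.0013), and Csrp1, which encodes a LIM domain protein, by 2.60 (SE 0.11, adjusted p = 9.8e-04). The metallothionein gene Mt1 was higher by 1.75 (SE 0.11, adjusted p = 0.0032), the integrin subunit gene Itga9 by 2.22 (adjusted p = 0.039) and the mitotic kinase gene Pbk by 1.63 (adjusted p = 0.031). Csrp1 was at 44.2, 44.1 and 43.9 TPM in Evi1 HSC and at 6.56 and 6.34 TPM in WT HSC replicates 1 and 2, but at 52.2 TPM in the library labelled WT KL replicate 1. Cenpp and Pbk were likewise low in WT HSC replicates 1 and 2 alone of the 9 libraries. In the library labelled WT KL replicate 1 they stood at 14.1 and 25.9 TPM, beside 15.2 to 17.8 and 24.7 to 28.8 TPM in Evi1 HSC. Mt1 was at 41.9 TPM there, under the 70.9 and 59.2 TPM of WT HSC replicates 1 and 2 and the 216 to 224 TPM of Evi1 HSC. Gata1 was at 8.92 TPM there and Klf1 at 13.6 TPM, between the Evi1 HSC and WT HSC values. Hebp1 was at 2.97 TPM there, near the 1.57 to 1.66 TPM of Evi1 HSC. In WT HSC replicates 1 and 2 it was at 15.5 and 13.97 TPM. Slc40a1, at 1.49 TPM there, also lay nearer Evi1 HSC (0.501 to 0.859 TPM) than WT HSC replicates 1 and 2. Itga9, at 13.4 TPM there, lay within the Evi1 HSC range. Atp1b2 and Dnajb4, at 13.5 and 17.03 TPM there, went the other way and lay between the values of WT HSC replicates 1 and 2. Mecom did not pass, at 0.54 (SE 0.20, adjusted p = 0.532), nor did Ly6a, at 1.20 (SE 0.40, adjusted p = 0.483).

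**Figure D3:**
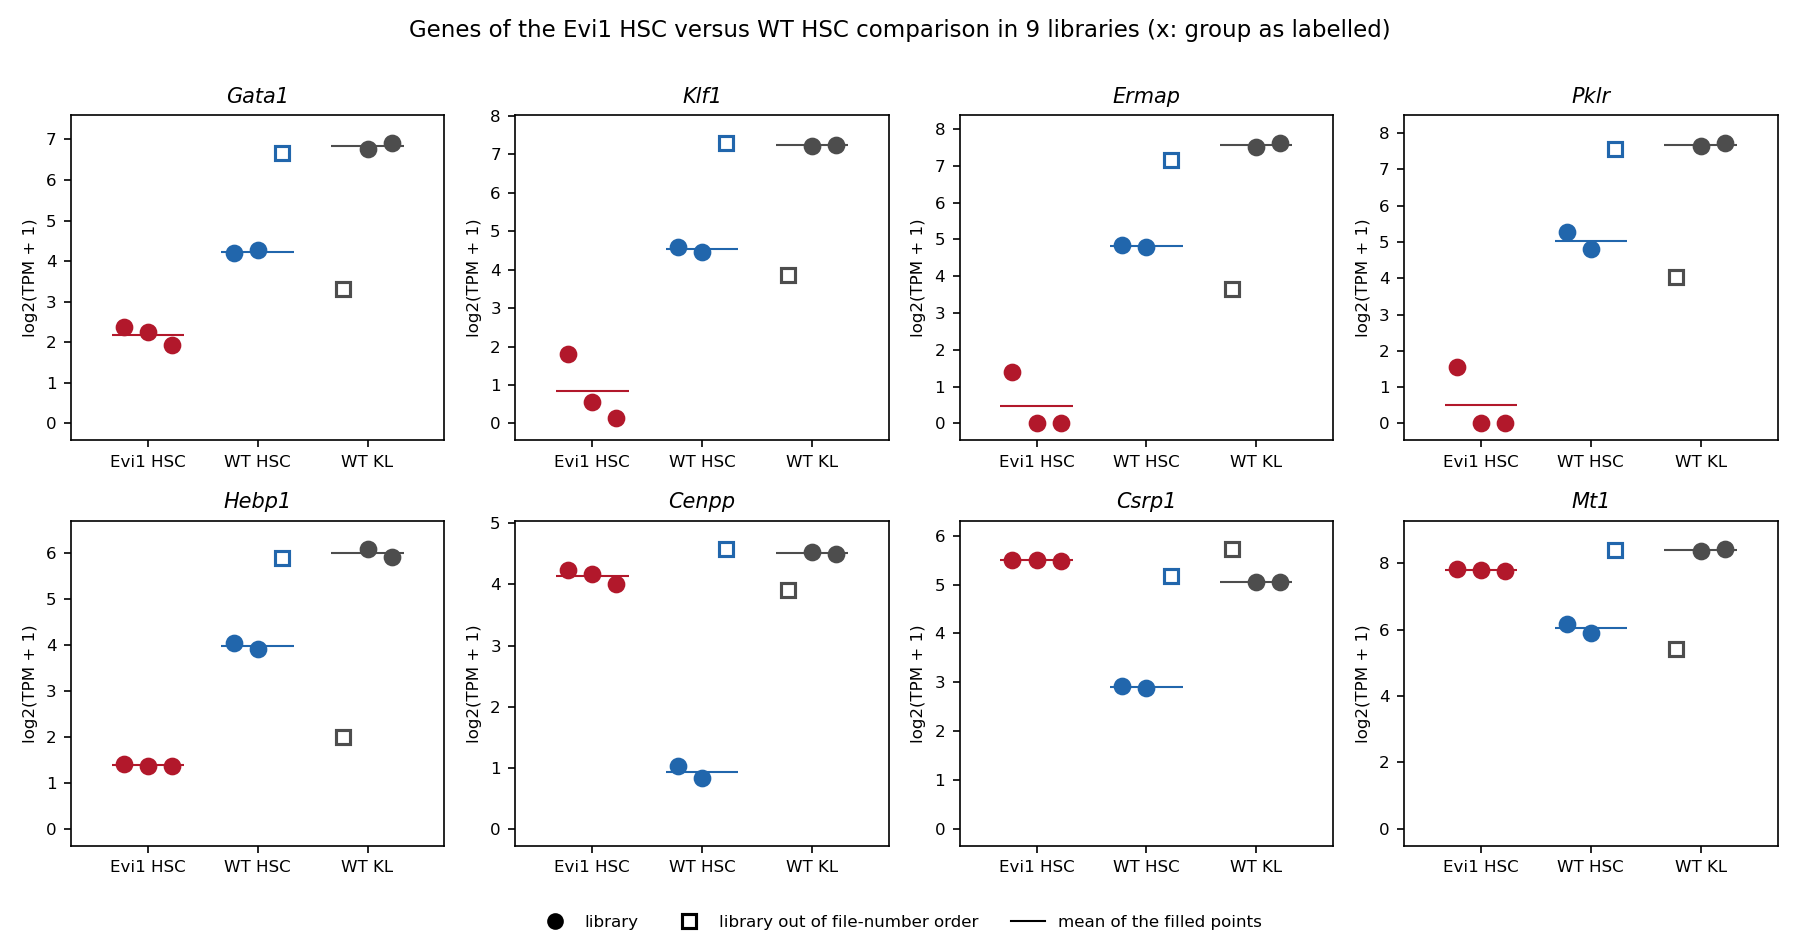
Values as log2(TPM + 1) per library for Gata1, Klf1, Ermap, Pklr, Hebp1, Cenpp, Csrp1 and Mt1, with the libraries grouped as labelled. Open squares are the 2 WT libraries out of file-number order, and lines are the mean of the filled points on that scale. Csrp1 lies at 43.9 to 44.2 TPM in Evi1 HSC and at 6.34 and 6.56 TPM in WT HSC replicates 1 and 2, with the library labelled WT KL replicate 1 at 52.2 TPM.

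The 40 calls depended on the model and on single libraries. All fits described here left out the library labelled WT KL replicate 1, in which Cenpp stood near and Csrp1 above its Evi1 HSC values. With a replicate block 0 genes were called, the smallest adjusted p being 0.0703. Egfp was among the genes at that value, at 4.32 (SE 0.21, against 4.36 and 0.18 without the block). Evi1 HSC and WT embryos differed in genotype, and WT HSC and WT KL replicate 2 differed in sex by Xist and Ddx3y. The replicate numbers in that block therefore did not mark a shared embryo, and whether they marked a shared day is not known. A fit on the compared groups alone called 6 genes, 5 higher and 1 lower, with Hebp1 kept (adjusted p = 0.036), and Gata1, Klf1, Ermap and Pklr lost (adjusted p = 0.125, 0.163, 0.138 and 0.138). With 1 library left out, 20 genes were called without Evi1 HSC replicate 1 (4 higher, 16 lower), 12 without replicate 2 (4 and 8) and 13 without replicate 3 (5 and 8). Without WT HSC replicate 1 there were 5 (5 higher, 0 lower), without WT HSC replicate 2 there were 27 (17 and 10), and without WT KL replicate 2 or replicate 3 there were 6 (5 and 1), so the excess of lower genes did not hold in these 4 fits. Egfp, Cenpp, Csrp1 and Mt1 were called in each of the 7 fits that left out 1 library and in that on the compared groups, but not with the block (adjusted p = 0.0703, 0.0703, 0.0703 and 0.0818). With 1 library left out, Hebp1 was called in all but that without WT HSC replicate 1 (adjusted p = 0.055). Gata1 lost its call without Evi1 HSC replicate 2 (adjusted p = 0.060), WT HSC replicate 1 (0.129), WT HSC replicate 2 (0.089), WT KL replicate 2 (0.096) or WT KL replicate 3 (0.091), while its log2 fold change ran from −2.08 to −2.00 in these fits. Klf1, Ermap and Pklr kept theirs only without Evi1 HSC replicate 1 (adjusted p = 0.0038, 0.0013 and 0.0029), and without other libraries their adjusted p reached 0.215, 0.160 and 0.160. There Klf1 ran from −3.75 to −3.34, Ermap from −4.38 to −4.12 and Pklr from −4.76 to −4.26, so precision was lost more than the differences. Itga9, Pbk, Dnajb4, Nmnat3, Cgrrf1, Epor and Slc40a1 lost theirs without any 1 library, each still in the same direction.

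By gene list, 9 libraries as labelled gave 14 of 17 lists that passed, 9 higher and 5 lower in Evi1 HSC, with no member called over all genes. The erythroid list had a median log2 fold change of −1.97 (adjusted p = 1.5e-09), with 3 members lower adjusted over the list alone. The stem cell, interferon response and endothelial lists had medians of 1.60, 1.47 and 1.57 (adjusted p = 0.0011, 8.7e-09 and 4.7e-06), with 0 members adjusted over the list alone. The median over all genes was 0.11. None of the 14 passed with an estimated correlation (smallest adjusted p = 0.553) or with fry. The count was 9 without Evi1 HSC replicate 3 or WT KL replicate 2, and 4 without the library labelled WT HSC replicate 3.

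Without the 2 libraries, 5 lists passed, and the stem cell list was not among them. Other splits of the same Evi1 HSC and WT HSC libraries gave 4 to 10 lists. The count of lists therefore does not set the real grouping apart. Of 24 measured erythroid genes, 4 fell (Gata1, Klf1, Epor and Ermap), none rose and 20 were not called, and 11 fell adjusted over the list alone. Their median log2 fold change was −1.18 (camera, adjusted p = 3.0e-09, and adjusted p = 0.277 with an estimated correlation). The adult beta globin Hbb-bt did not follow, at 1429, 681 and 861 TPM in Evi1 HSC and 545 and 619 TPM in WT HSC replicates 1 and 2. It was at 2280 TPM in the library labelled WT KL replicate 1. Interferon response genes were higher as a list, with a median of 0.86 over 23 measured members (adjusted p = 5.5e-12, and adjusted p = 0.258 with an estimated correlation). Of its members 0 were called with limma over all genes and 0 adjusted over the list alone. Ifitm3, an antiviral membrane protein, was at 353, 518 and 361 TPM in Evi1 HSC and at 241 and 246 TPM in WT HSC replicates 1 and 2 (adjusted p = 0.490). B2m, the class I light chain, was at 690, 498 and 409 TPM against 340 and 358 TPM (adjusted p = 0.535). Both lists passed in every fit that left out 1 library, but the interferon median became 0.55 without Evi1 HSC replicate 2. Fry gave adjusted p of 0.034 and 0.031 for them.

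The other 3 lists that passed were higher in Evi1 HSC, and each lost its call without 1 library. The 18 G2 and M phase genes had a median of 0.28 (adjusted p = 8.5e-06, and adjusted p = 0.287 with an estimated correlation). Without WT HSC replicate 2 it was 0.08 (adjusted p = 0.106). The 21 endothelial genes had a median of 0.35 (adjusted p = 1.4e-04, and adjusted p = 0.369 with an estimated correlation), with 1 member higher adjusted over the list alone. Without WT HSC replicate 1 it was −0.08 (adjusted p = 0.846). The 6 lymphoid genes had a median of 0.47 (adjusted p = 0.017, and adjusted p = 0.279 with an estimated correlation). Without WT HSC replicate 1 it was 0.34 (adjusted p = 0.133). No member of these 3 lists was called over all genes. Without Evi1 HSC replicate 2, 10 lists passed in all, and without WT HSC replicate 2, 8 passed.

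Lists that did not pass had medians near 0. They were the stem cell list (27 genes, median 0.04, adjusted p = 0.224), reported Evi1 targets (13 genes, 0.06, 0.311), Hox cluster (13 genes, 0.20, 0.224), fetal programme (13 genes, 0.07, 0.310), megakaryocyte (15 genes, −0.16, 0.235) and granulocyte and monocyte genes (18 genes, 0.02, 0.985). Arterial and haemogenic endothelium (7 genes, −0.01, 0.561, with the test pointing upward), S phase (18 genes, −0.07, 0.111), immediate early (15 genes, 0.15, 0.283), TGF-beta signalling (14 genes, 0.12, 0.109), ribosomal protein (80 genes, −0.01, 0.769) and mitochondrially encoded genes (37 genes, −0.14, 0.283) did not pass either. In none of these lists was a member called, over all genes or adjusted over the list alone.

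The WT HSC against WT KL comparison sets the stem cell gate beside committed progenitors of the same genotype. With the 9 libraries as labelled, 1 gene was called, the predicted transcript Gm47313, which lies outside the naming rule and was picked out after its values were seen. It was at 24.3, 17.8 and 25.5 TPM in the libraries labelled WT HSC and listed at 0 in all 3 labelled WT KL (adjusted p = 2.0e-04), so unlike the gate genes it followed the labels. Mecom, Hlf and Mpo did not pass in this fit. In it 282 of the 19461 tested genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance gives. Leaving out WT HSC replicate 2 gave 2 genes, and leaving out the library labelled WT HSC replicate 3 gave 4.

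Without the 2 libraries, 7307 genes were called, 5203 higher and 2104 lower in WT HSC. Genes of the stem cell list were higher, with Mecom up by 6.88 (SE 0.22, adjusted p = 2.2e-05) and Hlf by 5.83 (adjusted p = 2.2e-05). Esam, an adhesion molecule of endothelial and stem cells, was up by 6.17 (adjusted p = 9.9e-06). Hlf lies on chromosome 11 from 90336536 to 90390895 (minus strand) and Esam on chromosome 9 from 37528078 to 37538319 (plus strand). Adgrl4 was up by 7.01, Gcnt2 by 6.57, Gimap6 by 6.51, Mycn by 6.14, Serpina3g by 6.05, Ifitm1 by 5.89 and Tbxas1 by 5.76 (adjusted p of 9.9e-06 to 1.0e-04). Among the gate genes, Ly6a was higher by 4.0 (adjusted p = 8.5e-04), Kit by 1.34 (adjusted p = 0.0084) and Slamf1 by 1.94 (adjusted p = 0.0090), and Cd48 fell by 2.07 (adjusted p = 9.0e-04).

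Granulocyte genes were lower. Elane, the neutrophil elastase, fell by 6.15 (adjusted p = 1.8e-04), Mpo fell by 5.37 (adjusted p = 9.6e-04) and Ms4a3 fell by 5.02 (adjusted p = 4.0e-04). S100a8, Ctsg, S100a9, Stfa1 and Cstdc5 were listed at 0 in WT HSC replicates 1 and 2. In WT KL replicates 2 and 3, S100a8 was at 492 and 110 TPM, Ctsg at 180 and 91.0 TPM, and S100a9 at 266 and 25.6 TPM. Stfa1 was at 110 and 30.8 TPM there and Cstdc5 at 84.0 and 13.8 TPM. Add2 fell by 4.94 and Atp8b4 fell by 4.61 (adjusted p = 7.4e-05 and 4.5e-04).

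The count was 4536 without WT HSC replicate 2, 4493 without WT KL replicate 2 and 4291 without WT KL replicate 3. As deposited, the median log2 fold change over all genes was 0.26, and it was −0.03 after median-of-ratios rescaling and −0.10 after quantile normalisation. The share of calls that were higher in WT HSC went with it, from 71.2% to 49.3% (4085 higher and 4207 lower) and 48.7% (2999 higher and 3155 lower).

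In the fit over 9 libraries as labelled, 14 lists passed in this comparison, 8 higher and 6 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.553) or fry. The count was 3 without WT HSC replicate 2 and 5 without WT KL replicate 2. Without the 2 libraries 16 lists passed, 10 higher and 6 lower. Medians given here for the 7 libraries are relative to the all-gene median. Stem cell genes rose in 26 of 27 cases and Hox cluster genes in 13 of 13, Hoxa9 by 5.14 (26 and 13 adjusted over the list alone). Their medians were 4.31 and 2.42 (adjusted p = 3.5e-15 and 5.8e-07, and adjusted p = 0.258 for both with an estimated correlation). Reported Evi1 targets rose in 10 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone), Sox4 by 2.67. Fetal programme genes rose in 8 of 13 cases (9 up and 1 down adjusted over the list alone), the RNA-binding protein gene Igf2bp2 by 4.46. Medians of these lists were 2.15 and 2.02 (adjusted p = 7.2e-04 and 0.0020, and adjusted p = 0.277 for both with an estimated correlation). Of the endothelial list 15 of 21 genes rose and of the arterial and haemogenic endothelium list 6 of 7 (17 and 6 adjusted over the list alone), Tek by 4.76 and Neurl3 by 5.20. Here the medians were 2.54 and 1.63 (adjusted p = 1.9e-07 and 0.0030, and adjusted p = 0.277 for both with an estimated correlation). Lymphoid genes rose in 5 of 6 cases, Ltb by 4.41, and interferon response genes in 18 of 23, Ifitm3 by 4.24 (5 and 20 adjusted over the list alone). They had medians of 1.80 and 1.57 (adjusted p = 0.0097 and 5.6e-06, and adjusted p = 0.277 for both with an estimated correlation).

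Immediate early genes rose in 9 of 15 cases, Jund by 1.93 (11 adjusted over the list alone). Their median was 1.23 (adjusted p = 0.0088, and adjusted p = 0.393 with an estimated correlation). Megakaryocyte genes rose in 8 of 15 cases (9 adjusted over the list alone). With a median of 1.08, that list had an adjusted p = 0.025 (and adjusted p = 0.277 with an estimated correlation). It did not pass after quantile normalisation (adjusted p = 0.054) or without WT KL replicate 2 (adjusted p = 0.051). TGF-beta signalling genes rose in 6 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone). As a list they did not pass (median 0.93, adjusted p = 0.104), though they did after quantile normalisation (adjusted p = 0.048).

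Among lists that were lower, erythroid genes fell in 14 of 24 cases and rose in 2 (15 and 3 adjusted over the list alone). Gata1 fell by 2.60, and the carbonic anhydrase gene Car1 fell by 3.64. The median was −2.39 (adjusted p = 2.7e-07, and adjusted p = 0.277 with an estimated correlation). Granulocyte and monocyte genes fell in 11 of 18 cases and rose in 3 (11 and 4 adjusted over the list alone). Their median was −2.27 (adjusted p = 1.8e-05, and adjusted p = 0.277 with an estimated correlation). S phase genes fell in 14 of 18 cases and G2 and M phase genes in 9 of 18 (14 and 10 adjusted over the list alone). Rrm2 fell by 1.74, and Ccnb1 fell by 1.14. The medians were −0.94 and −0.98 (adjusted p = 6.9e-09 and 7.6e-07, and adjusted p = 0.258 and 0.277 with an estimated correlation). Mitochondrially encoded genes fell in 16 of 37 cases (20 adjusted over the list alone), and mt-Nd1 fell by 1.32. As a list they had a median of −1.23 (adjusted p = 5.3e-12, and adjusted p = 0.258 with an estimated correlation). Ribosomal protein genes fell in 10 of 80 cases (8 adjusted over the list alone), and Rps2 fell by 1.54. That list had a median of −0.29 (adjusted p = 9.4e-04, and adjusted p = 0.564 with an estimated correlation), and after quantile normalisation it pointed upward and did not pass (adjusted p = 0.097).

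In the Evi1 HSC against WT KL comparison, which places the Evi1 stem cell gate beside committed progenitors, Egfp and Gm47313 were called with the 9 libraries as labelled. Egfp was higher by 4.46 (adjusted p = 3.4e-04), and Gm47313 was at 17.1, 19.2 and 19.4 TPM in Evi1 HSC and listed at 0 in the 3 libraries labelled WT KL (adjusted p = 3.2e-04). Mecom did not pass, at 5.32 (adjusted p = 0.310). Specc1 came closest of the lower genes, at −3.33 (adjusted p = 0.061). At an unadjusted p under 0.05, 2956 genes differed, and without the library labelled WT KL replicate 1 the count of calls was 96, with 35 higher and 61 lower.

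Without the 2 libraries, 8863 genes were called, 6087 higher and 2776 lower in Evi1 HSC. Mecom was up by 7.42 (SE 0.20, adjusted p = 8.1e-06), Adgrl4 by 7.14, Gcnt2 by 6.65, Esam by 6.52 and Gimap6 by 6.46. Mycn was up by 6.11, Ifitm1 by 5.89, Hlf by 5.83, fibronectin (Fn1) by 5.82 and Pglyrp2 by 5.79, and adjusted p for these 10 genes were 4.7e-06 to 1.7e-04. Ly6a was up by 5.20 (adjusted p = 1.3e-04), Kit by 1.19 (adjusted p = 0.0074) and Slamf1 by 2.43 (adjusted p = 0.0019), and Cd48 fell by 1.74 (adjusted p = 8.1e-04). Among the genes that fell, Pklr was at −7.16, Ermap at −7.10, Klf1 at −6.39, Add2 at −5.85 and Atp1b2 at −5.81. Of the granulocyte genes, Elane was at −5.91 and Mpo at −5.80 (adjusted p of 1.9e-05 to 3.2e-04 for these 7). S100a8, Ctsg and S100a9 were listed at 0 in the 3 Evi1 HSC libraries.

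The count was 5866 without WT KL replicate 2 and 5641 without WT KL replicate 3. Over all genes the median log2 fold change was 0.28 as deposited, −0.02 after median-of-ratios rescaling and −0.08 after quantile normalisation, and the share of calls that were higher went from 68.7% to 49.2% (4672 higher and 4816 lower) and 47.7% (3663 higher and 4014 lower).

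As labelled, 15 lists passed, 9 higher and 6 lower in Evi1 HSC, and 0 with an estimated correlation (smallest adjusted p = 0.553) or fry. Without the 2 libraries all 17 passed, 11 higher and 6 lower, with medians again relative to that over all genes. All 27 stem cell genes and all 13 Hox cluster genes rose, Hoxa9 by 5.08 (27 and 13 adjusted over the list alone). Their medians were 4.27 and 2.68 (adjusted p = 5.9e-14 and 1.3e-06, and adjusted p = 0.258 for both with an estimated correlation). All 23 interferon response genes rose, Ifitm3 by 4.96, and so did 5 of 6 lymphoid genes (23 and 5 adjusted over the list alone). These had medians of 2.29 and 2.25 (adjusted p = 8.1e-08 and 0.0031, and adjusted p = 0.277 for both with an estimated correlation). Endothelial genes rose in 20 of 21 cases and arterial and haemogenic endothelium genes in 7 of 7 (20 and 7 adjusted over the list alone). The medians were 2.89 and 1.60 (adjusted p = 2.9e-08 and 0.0031, and adjusted p = 0.277 for both with an estimated correlation). Reported Evi1 targets rose in 11 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone), Setbp1 by 4.25. Fetal programme genes rose in 8 of 13 cases (10 adjusted over the list alone). Both had medians of 2.06 (adjusted p = 9.8e-04 and 0.0020, and adjusted p = 0.277 for both with an estimated correlation). Immediate early genes rose in 12 of 15 cases (12 adjusted over the list alone). Their median was 1.64 (adjusted p = 0.0057, and adjusted p = 0.374 with an estimated correlation).

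Erythroid genes fell in 15 of 24 cases and rose in 3 (15 and 3 adjusted over the list alone). Gata1 fell by 4.64, and the transferrin receptor gene Tfrc fell by 3.86. The median was −4.16 (adjusted p = 2.0e-08, and adjusted p = 0.277 with an estimated correlation). Granulocyte and monocyte genes fell in 11 of 18 cases and rose in 4 (11 and 4 adjusted over the list alone). Their median was −2.08 (adjusted p = 3.6e-05, and adjusted p = 0.278 with an estimated correlation). S phase genes fell in 14 of 18 cases, and mitochondrially encoded genes in 26 of 37 (14 and 29 adjusted over the list alone). Here the medians were −1.07 and −1.19 (adjusted p = 8.1e-09 and 6.9e-12, and adjusted p = 0.258 for both with an estimated correlation). G2 and M phase genes fell in 6 of 18 cases (4 adjusted over the list alone). They had a median of −0.65 (adjusted p = 0.0014, and adjusted p = 0.417 with an estimated correlation), with adjusted p = 0.137 after quantile normalisation. Ribosomal protein genes fell in 17 of 80 cases and rose in 5 (13 and 0 adjusted over the list alone). That list had a median of −0.31 (adjusted p = 0.0012, and adjusted p = 0.564 with an estimated correlation), and after quantile normalisation it pointed upward and did not pass (adjusted p = 0.229).

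Megakaryocyte genes rose in 9 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone). Their median was 1.07 (adjusted p = 0.048, and adjusted p = 0.277 with an estimated correlation). The list did not pass after quantile normalisation (adjusted p = 0.086), nor without Evi1 HSC replicate 2 (adjusted p = 0.051), Evi1 HSC replicate 3 (adjusted p = 0.056) or WT KL replicate 2 (adjusted p = 0.085). TGF-beta signalling genes rose in 8 of 14 cases and fell in 1 (8 and 1 adjusted over the list alone), Smad3 by 2.67. With a median of 1.17 the list had an adjusted p = 0.032 (and adjusted p = 0.277 with an estimated correlation), and it did not pass without WT KL replicate 2 (adjusted p = 0.050).

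The Evi1 HSC libraries correlated more with the WT HSC than with the WT KL libraries, by 0.0465 in mean r as labelled and by 0.143 without the 2 libraries. As labelled, that difference was 0.0932 without the library labelled WT HSC replicate 3 and 0.0958 without the library labelled WT KL replicate 1. It was 0.0239 and 0.0225 without WT HSC replicates 1 and 2, and 0.0225 and 0.0213 without WT KL replicates 2 and 3. Markers of other cell types, summed over each untested list, were low in all libraries. The sums were 0.827 to 2.22 TPM for stroma, 1.32 to 14.8 TPM for MHC class II and 4.25 to 51.0 TPM for hepatocytes. For macrophages they were 11.3 to 27.9 TPM, and for mast cells, basophils and eosinophils 3.71 to 60.4 TPM. The highest hepatocyte sum was in the library labelled WT KL replicate 1.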

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

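The alternatives run on 7 libraries, without the libraries labelled WT HSC replicate 3 and WT KL replicate 1, were chosen after the data were seen, and the others were planned. Comparisons are in the order Evi1 HSC against WT HSC, WT HSC against WT KL and Evi1 HSC against WT KL. Causes were not tested except where fewer samples or genes are the change itself. Depth limits all of it in an unknown way, since TPM keeps none.

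With all 9 libraries as labelled, the genes called were 1, 1 and 2. Without both libraries they were 40, 7307 and 8863, and array weights, which set a weight for each library from the data, gave 189 (91 higher, 98 lower), 10145 (6843 and 3302) and 9987 (6678 and 3309). No filter gave 3, 2 and 6, and quantile normalisation gave 6 in the last comparison. A pseudocount of 0.1 gave 1 in the last comparison and 0 in the first. With a pseudocount of 1, 907 of 19461 genes in the first had an unadjusted p under 0.05 (limma), fewer than chance gives. Leaving out 1 library gave 1 to 3, 1 to 4 and 2 to 96. Lists passing went from 14, 14 and 15 to 0, 0 and 0 with an estimated correlation and with fry, and in the first comparison to 9 with no filter, 8 with array weights and 5 without both libraries. Leaving out 1 library gave 4 to 15, 3 to 16 and 12 to 16 lists. The difference in mean r of 0.0465 became 0.0578 and 0.0402 with pseudocounts of 0.1 and 5, 0.0254 with no filter, 0.0802 with a filter at 5 TPM, 0.143 without both libraries and 0.0527 as Spearman's rho, and 0.0213 to 0.0958 with 1 library left out.

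Over the 7 libraries, the 40 genes of the first comparison became 17 with a pseudocount of 5, 73 with no filter, 6 in a fit on the compared groups alone and 1 with all 9 libraries, where the other comparisons had 1 and 2. Leaving out 1 library gave 5 to 27, 4291 to 7324 and 5641 to 8703 genes, and 4 to 10, 15 to 16 and 15 to 17 lists. Lists fell from 5, 16 and 17 to 0, 0 and 0 with an estimated correlation, and with fry they were 2, 16 and 15. The first comparison had 14 with all 9. Between WT HSC and WT KL, TGF-beta signalling passed with fry (adjusted p = 5.6e-04) and ribosomal protein genes did not (fry, adjusted p = 0.478). The difference in mean r of 0.143 became 0.179 and 0.122 with pseudocounts of 0.1 and 5, 0.0791 with no filter, 0.243 with a filter at 5 TPM, 0.0465 with all 9 and 0.165 as Spearman's rho, and 0.138 to 0.146 with 1 library left out.

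Replicate numbers are shared between the groups, but no label ties them to an embryo. The libraries labelled WT HSC and WT KL differed in sex within replicate 1 and within replicate 2, so those pairs did not share an embryo. Deviations of same-numbered libraries from their labelled group means correlated by −0.64 to 0.70, against −0.85 to 0.73 for others. Those means held the libraries that went against their labels, so these values cannot show whether the numbers mark a pairing. A replicate block gave 1, 1 and 2 genes over 9 libraries and 0, 4947 and 7526 over 7.

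Single genes kept direction and call in 381 of 457 values over 9 libraries (2 lost and 69 gained a call, 5 reversed) and in 1887 of 2170 over 7 (275 lost, 1 gained, 7 reversed). With 1 library left out, the counts were 400 of 414 (0 lost, 6 gained, 8 reversed) and 1393 of 1526 (126 lost, 0 gained, 7 reversed). None of the reversed values was called. Over 9 libraries, Slamf1 between WT HSC and WT KL reversed to −0.038 with a pseudocount of 5 and to −0.028 with quantile normalisation, Cd48 between Evi1 HSC and WT HSC to 0.47 with array weights, and without both libraries Kit to −0.15 and Cd48 to 0.33. Over 7 libraries, Axl between WT HSC and WT KL reversed to −0.060 with quantile normalisation, Egfp there to 0.067 with the block, and Slc40a1 there to 0.013 with all 9. Between Evi1 HSC and WT HSC, Hlf reversed to 0.0084 with array weights and to 2.24 with all 9, Kit to 0.37 and Cd48 to −0.43. With 1 library left out, the values over 9 libraries ran from −0.15 to 0.71 for Kit and −0.93 to 0.33 for Cd48 in the first comparison, and from −0.15 to 0.10 for Egfp and −0.39 to 1.35 for Slamf1 between WT HSC and WT KL. Over 7 they ran from −0.31 to 0.057 for Kit, −0.15 to 0.15 for Hlf and −0.10 to 1.22 for Egfl7 in the first comparison, and from −0.13 to 0.068 for Egfp between WT HSC and WT KL.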

Other observations

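The tests of explanations and the other splits of the samples given here were all chosen after the results were seen, and so were the genes described first. Each library held RNA of 1 sex type. Xist, the transcript of the inactive X chromosome, was at 194 to 372 TPM in 6 libraries, in which the Y-linked Ddx3y was listed at 0. In WT HSC replicate 1, WT KL replicate 2 and Evi1 HSC replicate 3, Xist was at 0.340 TPM or less and Ddx3y at 25.3, 14.1 and 17.2 TPM. The neighbouring metallothionein genes Mt1 and Mt2 went apart in Evi1 HSC. Mt1 was at 216 to 224 TPM against 70.9 and 59.2 TPM in WT HSC replicates 1 and 2, while Mt2 was at 14.3, 1.46 and 3.72 TPM against 43.5 and 27.7 TPM (limma over 7 libraries, adjusted p = 0.33). They are paralogs, and how shared reads were counted is not given in the sources used here.

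Stab2 and Lyve1, which are used as markers of sinusoidal endothelium, differed between WT HSC replicates 1 and 2, and they are 2 single genes. Stab2 was at 10.01, 10.8 and 10.5 TPM in Evi1 HSC and at 8.26 TPM in WT HSC replicate 2, but at 0.175 TPM in WT HSC replicate 1 and 0.580 TPM in the library labelled WT KL replicate 1. Lyve1 was at 13.03, 9.995 and 9.13 TPM in Evi1 HSC, at 8.58 and 0.393 TPM in WT HSC replicates 2 and 1, and at 3.31 TPM in the library labelled WT KL replicate 1. The alpha globin Hba-a1 was at 1146 TPM in the library labelled WT KL replicate 1 and at 244 TPM in Evi1 HSC replicate 1, but at 2.40 and 2.03 TPM in Evi1 HSC replicates 2 and 3. The Notch receptor gene Notch1 was at 43.9, 24.6 and 50.9 TPM in Evi1 HSC and at 17.9 and 18.3 TPM in WT HSC replicates 1 and 2 (adjusted p = 0.438 over 7 libraries).

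The libraries labelled WT HSC replicate 3 and WT KL replicate 1 resembled the opposite WT gate. A mixture of both whole gates in each was argued against, because stem cell markers in the former and granulocyte and monocyte markers in the latter implied a median share of at most 0.000317 of the labelled gate's RNA (upper quartile 0.00182), though erythroid markers in the latter implied 0.0710 above Evi1 HSC (upper quartile 0.0846) and −0.0702 above WT HSC replicates 1 and 2 (upper quartile −0.00331). Loss of RNA or depth was argued against too, because the markers of the opposite gate were higher in both libraries, by a median of 4.68 or more on the log2 scale (lower quartile 3.78). TPM is a share of each library's total, so a loss that hits all genes alike does not raise 1 marker set. An exchange of labels or of tubes is a candidate explanation that the values fit: each library correlated more with the opposite group than with its own, by at least 0.127 in mean r, each has a partner out of place, and the column heading C_H3 in the file of WT HSC replicate 2 could be read as a control HSC library numbered 3, though no label explains it. Both libraries are female by Xist, so sex does not tell them apart. Gm47313 was listed at 0 in the 3 libraries labelled WT KL and at 17.8 to 25.5 TPM in those labelled WT HSC. It followed the labels, and so did other genes. Ndfip1 was at 2.26 to 5.19 TPM in the libraries labelled WT HSC and at 23.2 to 41.0 TPM in those labelled WT KL. Shoc2 (4.80 to 10.9 against 31.5 to 34.9 TPM) and Specc1 (2.41 to 4.22 against 14.1 to 35.0 TPM) also followed the labels. These others were not called, and they were picked out of 19461 tested genes for following the labels. Splits of the WT libraries that matched neither the labels nor an exchange called 0 to 2 genes each. Genes that follow the labels therefore do not decide against an exchange.

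Erythroid genes were lower in Evi1 HSC than in WT HSC replicates 1 and 2 as a list (camera, adjusted p = 3.0e-09, and adjusted p = 0.277 with an estimated correlation), with 4 of 24 members called lower, 20 not called, and the means of Hbb-bt and Hbb-bs 1.70 and 1.78 times as high in Evi1 HSC. Evi1 HSC replicate 1 was the highest for both. Hbb-bs overlapped, at 1188, 415 and 539 TPM in Evi1 HSC and 336 and 468 TPM in WT HSC replicates 1 and 2. Cells of the whole KL gate within the WT HSC libraries were argued against, because the granulocyte and monocyte markers implied a median share of 0 (quartiles −0.00240 and 0.00113) where the erythroid markers implied 0.132 (quartiles 0.0714 and 0.149). Erythroid progenitors alone in the WT HSC libraries, which the CD48 and Sca-1 gates would be meant to remove, stay open. The erythroid shares varied between genes more than the criterion for 1 share allowed. The criterion against such cells, a lower quartile at or under 0, was not met either, so that test was undecided. The erythroid shares lay above 0, but the choice of the 13 markers favours that. Each had a WT KL mean of at least 10 TPM and over 4 times the Evi1 HSC mean. That WT KL mean left out the library labelled WT KL replicate 1. Shares were measured above that same Evi1 HSC mean, and Hbb-bs and Hbb-bt were not among the markers. The library labelled WT KL replicate 1 implied a share of 0.0710 by the same genes, so WT libraries that resemble this gate may differ among themselves. An effect of Evi1 on erythroid genes also stays open, and with 2 WT HSC libraries it cannot be told apart from such cells. Only the Evi1 HSC group was sorted on GFP and carried Tie2-Cre, so Evi1 cannot be told apart from these either.

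Interferon response genes were higher in Evi1 HSC as a list, with 0 of 23 members called (camera, adjusted p = 5.5e-12, and adjusted p = 0.258 with an estimated correlation). A single Evi1 library as the whole source was argued against, because without Evi1 HSC replicate 2 the median was still 0.549 (lower quartile 0.463), against 0.856 with all 3, and the list passed (adjusted p = 3.6e-08, and adjusted p = 0.175 with an estimated correlation), a criterion set after the lower value was seen. A litter, day or background shared by the Evi1 libraries cannot be told apart from Evi1, since no label gives them: 17 of 23 members were above both WT HSC libraries in all 3 Evi1 HSC libraries, where chance gives 10% of genes. In the library labelled WT KL replicate 1, which has no Cre by its label, 17 of 23 members were also above both WT HSC libraries, and 13 of 23 were below all 3 Evi1 HSC libraries. The 10% does not apply to these counts, because chance gives larger shares for 1 library. Nor does it make a test of the 17 members, since it holds for each gene alone and members need not vary independently. An effect of Evi1 stays open and was not tested apart from these, nor from the GFP sort and Tie2-Cre, which only the Evi1 HSC group had.

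Other splits of the samples are too few for a share under 0.05 in any comparison, with 10 splits each, the real one included. For genes called, the real value and the highest of the other splits were 1 and 1 for Evi1 HSC against WT HSC, where 3 splits gave as many as the real one, and 2 and 0 for Evi1 HSC against WT KL, where 1 split did. For WT HSC against WT KL they were 1 and 10065, and 5 splits gave as many. The split with 10065 genes set WT HSC replicates 1 and 2 with the library labelled WT KL replicate 1 against the other WT libraries, which points to a structure of the samples. For lists, the real value and the highest other were 14 and 14, 14 and 16, and 15 and 17 in the 3 comparisons in the order Evi1 HSC against WT HSC, WT HSC against WT KL and Evi1 HSC against WT KL, with 2 splits as large in each. Over the 7 libraries, Evi1 HSC against WT HSC gave 40 genes and the highest other split gave 6, so 1 split reached the real count. For lists it gave 5 and the highest other split gave 10, and 8 splits gave as many as the real one, which counts the real one.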
